A study of Mus musculus with 8 samples.

How the data were processed

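Bulk RNA sequencing of liver was used to compare 4 groups of 2 mice, control and sudachitin at ZT6 and ZT18. Per the labels' protocols, RNA with an integrity number above 9.0 was used, 2 µg of it went into poly(A)-selected libraries without strand information, and these were read as 150-base pairs on a NovaSeq instrument. Each sample title names a mouse, so the 2 libraries of a group were taken as separate animals. Groups and replicate numbers came from the sample titles. The meaning of the codes within the titles was not given in the sources used here.

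The deposited tables hold 55421 transcripts of mouse genome GRCm38 (mm10), 1 canonical transcript per gene model, in 8 library columns each. Reads were trimmed with Trimmomatic 0.39, aligned with STAR 2.7.2a and counted with HOMER, whose version was not given, per the submitters' processing notes, which name the tools without their roles. The first deposited table holds estimated counts in exons, not normalized and in steps of 0.5, per the file headers and the values. In each library 19.69% to 21.89% of the values ended in 0.5, and all were rounded to whole numbers, with 0.5 rounded up, before testing. The second deposited table holds FPKM, the count divided by exon length and scaled to the library total in the column header, and it differed from that calculation by at most 4e-11. Whether the counting used strand, and how it treated reads with several positions, was not given in the sources used here. Counts of transcripts that overlap on opposite strands therefore cannot be told apart, and 6844 transcripts have an exon overlapping an opposite-strand exon and 2465 one on the same strand. Of the transcript identifiers, 55103 were in GENCODE mouse release 21, and 54910 of these had the same coordinates and strand there. Counts in exons came to 13914116 and 15093803 in control ZT6, 17759630.5 and 14440239.5 in control ZT18, 16271289 and 14448504 in sudachitin ZT6 and 17483095 and 16913365 in sudachitin ZT18 livers, which was 43.57% to 47.77% of the totals in the headers. No 2 libraries were identical, and the 2 mice of each group differed by more than sampling noise, with a chi-square per degree of freedom of 17.5 for control ZT6, 58.8 for control ZT18, 19.9 for sudachitin ZT6 and 27 for sudachitin ZT18.

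Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM factors (0.966 to 1.016), the default filter on low counts by group, which left 14506 transcripts, and the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. The SE beside an edgeR log2 change is the size of that change divided by the square root of the F statistic. It is derived in this way because the test itself gives no standard error. A model with 4 group means gave the comparisons of treatment at each time, of time within each treatment and the interaction, and an additive model of treatment and time gave the effects over both levels of the other factor. All 8 libraries entered each fit, so that the groups shared 1 estimate of the spread. Expression is given in TMM-scaled CPM, a count relative to the size of its library. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Of 36 lists, which hold 600 symbols of which 597 were in the table, 33 had at least 5 tested members and were tested. Adjusted p-values of lists are over the lists of a comparison, and counts adjusted over the list alone are over the members of that list. For the 113 symbols with more than 1 transcript the one with the highest mean count was used in lists.

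The groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. In each comparison except the 2 additive ones, the rule names up to 10 genes with the largest rise and up to 10 with the largest fall among those with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups. For the interaction there is no condition on overlap. Symbols of predicted genes, meaning Gm, AC, AL, BC, AA, AW, AI, AU or RP followed by digits or a symbol ending in Rik, and transcripts without a symbol were left out. Every core clock gene is named, as are up to 4 members of each other list with the smallest p; one gene so named is not reported here. Where fewer than 5 genes passed, the 5 with the smallest p are named as not passing. Gm42418, Gm26917, CT010467.1, Rn7sk, mt-Rnr1, mt-Rnr2 and the male-biased and female-biased genes whose levels are given per library were named after their values were seen.

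Alternatives were DESeq2 1.42.0 with its own size factors, edgeR with median-of-ratios factors or with total counts, no filter on low counts, a filter of at least 5 CPM in 2 libraries, only the groups compared, the replicate number as a block, a test against a fold of 1.2, and limma-trend on log2(FPKM + 0.1) or log2(FPKM + 1). Leaving out each library in turn leaves 1 mouse in a group, which is then assumed to vary like the mice of the other groups. An alternative without Gm42418, AY036118, CT010467.1 and Lars2 was added after the data were seen.

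The tests were tested on simulated counts with the means and library sizes of these livers, with 200 genes changed, 100 by a fold of 2 and 100 by a fold of 4. Apart from the change, each gene had the same mean in all groups, and genes varied independently of each other. Only genes above a minimum level were changed, and no library was made to stand apart, so the shares found may not hold for the livers. The share found was 56% and 90% for treatment at ZT6 (14295 genes), 52% and 91% for treatment at ZT18 (14264 genes), 52% and 86% for time in control (14294 genes) and 46% and 90% for time in sudachitin livers (14277 genes). It was 12% and 71% for the interaction (14264 genes), 73% and 99% for treatment over both times (14300 genes) and 79% and 96% for time over both treatments (14301 genes). Of the calls on simulated counts, 11 of 157, 14 of 157, 15 of 153 and 18 of 154 were false in the 4 comparisons within a time or treatment, in the order above, 4 of 87 for the interaction, 10 of 182 for treatment over both times and 14 of 189 for time over both treatments. In all but the interaction this share was above the threshold of 0.05.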

Results

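Liver RNA was profiled from 8 male C57BL/6J mice on a high-fat diet, in which 45% of the calories came from fat. Mice bought at 4 weeks of age were gavaged every other day, between zeitgeber time (ZT, hours after lights on) 8 and 10, with saline vehicle (cohort of 11) or with sudachitin at 100 mg per kg of body weight (cohort of 12). Sudachitin is a polymethoxyflavone, a plant flavonoid with several methoxy groups. Livers were taken at 30 weeks of age at ZT6, in the day, and at ZT18, in the night, and the sequenced libraries came from 2 mice in each of the 4 groups of treatment and time. The series asks how sudachitin acts on the liver clock and on metabolic gene expression, so the comparisons are sudachitin against control at each time, ZT18 against ZT6 under each treatment, the interaction of treatment and time, and the 2 effects averaged over the other factor. No code start in the sample titles occurs in more than 1 group, and the 2 mice of each ZT6 group share their code start. Cages or handling groups, if the codes mark them, therefore cannot be told apart from treatment or time in any comparison with a ZT6 group. The 2 mice of each ZT18 group differ in code start, so there such a difference cannot be told apart from that between mice. Libraries held 13914116 to 17759630.5 counts in exons. Over tested genes, the log2 expression of the 2 mice of a group correlated with r = 0.985 for control ZT6, 0.971 for control ZT18, 0.984 for sudachitin ZT6 and 0.983 for sudachitin ZT18, across genes, which are not independent replicates. Control ZT18 replicate 1 stood apart. In 38.2% of genes it was the highest or the lowest of the 8 libraries, against 17.4% to 27.7% for each other library and 25% by chance. Of 18 genes expressed more in male than in female liver, 15 were lower in it than in each of the other 7 libraries, and of 6 female-biased genes 5 were higher.

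Day and night differed in the circadian oscillator of both treatment groups. In control livers Nr1d1, which encodes the repressor REV-ERB alpha, fell by 4.47 on the log2 scale from ZT6 to ZT18 (SE 0.23, edgeR adjusted p = 0.00028), from 111 ± 12.5 to 5.02 ± 0.155 CPM (counts scaled to library size, mean ± SD, n = 2 mice). In sudachitin livers Nr1d1 fell by 4.04 (SE 0.22, edgeR adjusted p = 0.00051). Cry1, a repressor of the clock, rose by 2.10 (SE 0.14, adjusted p = 0.0016) in control and by 1.53 (SE 0.14, adjusted p = 0.0051) in sudachitin livers. Nr1d2, which encodes REV-ERB beta, fell by 1.46 (SE 0.13, adjusted p = 0.0056) in control and by 1.0 (SE 0.13, adjusted p = 0.029) in sudachitin livers. Of the 15 core clock genes tested, 2 rose, 2 fell and 11 did not pass over all genes in either treatment group. Adjusted over the list alone, 4 rose and 2 fell in control livers, and 6 rose and 3 fell in sudachitin livers. Per2, with log2 changes of 1.53 (SE 0.40, adjusted p = 0.18) in control and 1.77 (SE 0.40, adjusted p = 0.14) in sudachitin livers, did not pass over all genes, nor did Arntl, which encodes BMAL1, with 0.60 (SE 0.18, adjusted p = 0.24) and 0.50 (SE 0.18, adjusted p = 0.33). When each library was left out in turn, Nr1d1 passed every time in both treatments, with an adjusted p up to 0.0033 in control and 0.0049 in sudachitin livers. In control livers Cry1 passed every time and Nr1d2 did not without control ZT6 replicate 1 (0.065). In sudachitin livers Cry1 did not pass without sudachitin ZT6 replicate 1 (0.098) or 2 (0.071) or sudachitin ZT18 replicate 1 (0.062), and Nr1d2 did not without any library except the 2 ZT18 controls (0.076 to 0.29). On GRCm38, Nr1d1 lies at 98767932 to 98775333 on chromosome 11, Cry1 at 85131700 to 85185064 on chromosome 10 and Nr1d2 at 18204054 to 18239127 on chromosome 14. Arntl overlaps an antisense transcript, over 33 bases.

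**Figure D1:**
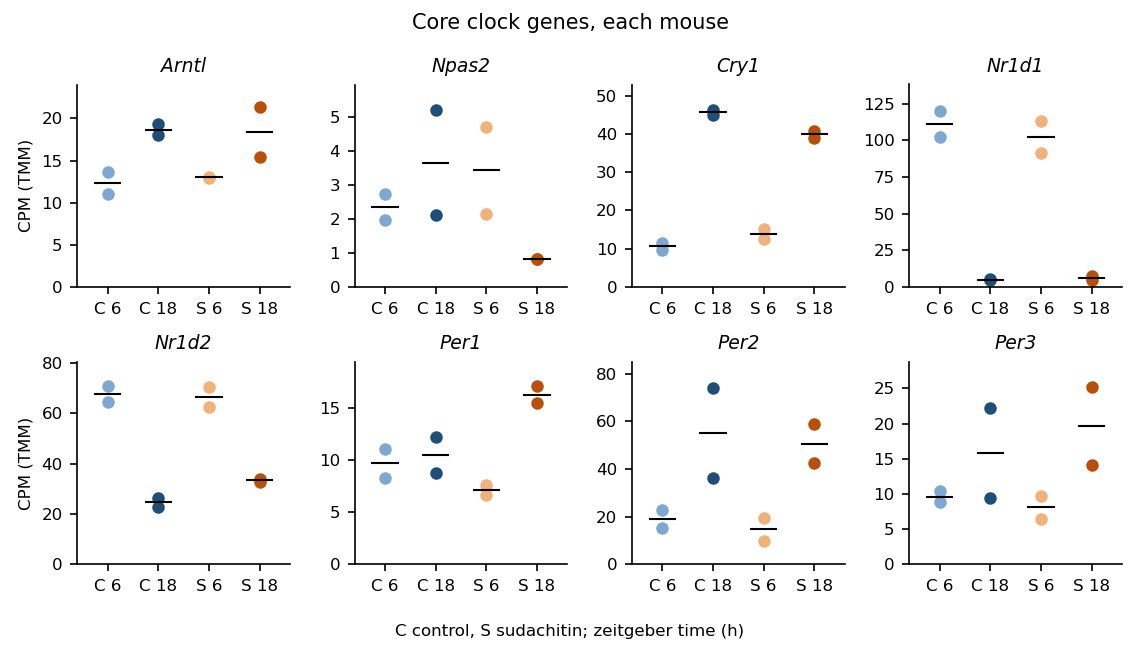
Expression in CPM (TMM-scaled, linear axis from 0) of 8 core clock genes in each mouse, with control (C) and sudachitin (S) livers at ZT6 and ZT18 on the horizontal axis. Each point is 1 mouse and each bar the mean of 2 mice; Nr1d1 stood at 111 CPM in control livers at ZT6 and at 5.02 CPM at ZT18, and at 102 and 6.19 CPM in sudachitin livers.

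Beyond the oscillator, genes of the unfolded protein response were among those that differed between ZT6 and ZT18 in control livers. Of 22 tested genes of the unfolded protein response and integrated stress response, 7 fell from ZT6 to ZT18, none rose and 15 did not pass; adjusted over the list alone, 13 fell. Hsp90b1, a chaperone, fell by 1.08 (SE 0.14, edgeR adjusted p = 0.021), Calr, the calcium-binding chaperone calreticulin, by 1.04 (SE 0.14, adjusted p = 0.023), Xbp1, a transcription factor of this response, by 0.85 (SE 0.13, adjusted p = 0.039), and Sdf2l1 fell by 2.62 (SE 0.44, adjusted p = 0.0499). Hsp90b1 overlaps exons of other genes on both strands, so that its counts are uncertain. Of 22 genes of fatty acid and triglyceride synthesis, Elovl6, a fatty acid elongase, rose by 1.92 (SE 0.30, adjusted p = 0.043) and 21 did not pass; adjusted over the list alone 4 rose. Of 18 clock output genes, 3 rose, 1 fell and 14 did not pass, and adjusted over the list alone 9 rose and 3 fell. Wee1, a kinase that delays mitosis, rose by 1.72 (SE 0.17, adjusted p = 0.0075), Usp2 by 2.53 (SE 0.42, adjusted p = 0.049) and Tspan4 by 1.05 (SE 0.17, adjusted p = 0.043), while Dbp, a transcription factor driven by the clock, fell by 2.41 (SE 0.27, adjusted p = 0.014). G0s2, an inhibitor of triglyceride lipase, rose by 1.07 (SE 0.16, adjusted p = 0.036), and Abcb11, the bile salt export pump, fell by 0.83 (SE 0.12, adjusted p = 0.036). Usp2, Tspan4, Dbp and Abcb11 each overlap an antisense transcript, and the libraries carry no strand, so their counts may include reads of that partner.

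In all, 76 of 14506 genes passed edgeR's quasi-likelihood test between ZT18 and ZT6 in control livers, 31 higher and 45 lower. Among gene lists tested with camera at a preset correlation, 8 of 33 ranked higher at ZT18 and 3 lower. The unfolded protein response ranked lower (adjusted p = 3.9e-09), as did cholesterol synthesis (0.0013) and male-biased genes (0.0021). Fatty acid and triglyceride synthesis (5.6e-05), oxidative phosphorylation (5.6e-05, with 42 of 42 members above 0), lipid droplet and uptake (0.00049), heat shock and cold-inducible genes (0.0011), cell cycle (0.0019), clock output (0.0021), glycolysis and glycogen (0.016) and female-biased genes (0.037) ranked higher. With an estimated correlation none passed, with an adjusted p of 0.62 to 0.68. Without control ZT18 replicate 1, the library with low male-biased genes, 4 of the 11 lists passed: the unfolded protein response (adjusted p = 3.5e-09), fatty acid and triglyceride synthesis (0.00034), clock output (0.0024) and cholesterol synthesis (0.014), while male-biased genes then ranked higher (0.81). When each library was left out in turn, the unfolded protein response and fatty acid and triglyceride synthesis passed every time. Clock output was at 0.082 without control ZT18 replicate 2 and cholesterol synthesis at 0.69 without control ZT6 replicate 1. The gene count was 5 and 6 without control ZT6 replicate 1 or 2, 47 and 323 without control ZT18 replicate 1 or 2, and 32 without either sudachitin ZT6 library. Across tools and filters it ranged from 4 with only the groups compared to 881 without a filter on low counts.

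In sudachitin livers 27 genes passed between ZT18 and ZT6, 16 higher and 11 lower. Nmrk1, a kinase that makes nicotinamide mononucleotide, rose by 2.02 (SE 0.18, edgeR adjusted p = 0.0051), and in control livers by 1.41 (SE 0.18, adjusted p = 0.021). Of 18 clock output genes, 3 rose, 1 fell and 14 did not pass, and adjusted over the list alone 11 rose and 2 fell: Wee1 rose by 1.42 (SE 0.17, adjusted p = 0.023), Tspan4 by 1.34 (SE 0.17, adjusted p = 0.027) and Por, the electron donor of cytochrome P450 enzymes, by 1.28 (SE 0.18, adjusted p = 0.041), and Dbp fell by 1.88 (SE 0.27, adjusted p = 0.042). G0s2 rose by 1.33 (SE 0.16, adjusted p = 0.026), and Agxt, a peroxisomal aminotransferase, fell by 1.16 (SE 0.15, adjusted p = 0.028). Of the 22 genes of the unfolded protein response, none passed over all genes, and 5 fell when adjusted over the list alone. With camera, 9 lists ranked higher and 2 lower at ZT18. Among them, heat shock and cold-inducible genes (adjusted p = 0.00011), clock output (0.00035), fatty acid and triglyceride synthesis (0.007), fatty acid oxidation and ketogenesis (0.013), lipid droplet and uptake (0.013), gluconeogenesis (0.013), glycolysis and glycogen (0.029) and male-biased genes (0.036) ranked higher, and interferon response (0.00035) and the unfolded protein response (0.028) lower. With an estimated correlation the adjusted p was 0.80 for each. Heat shock, clock output and interferon response passed with each library left out in turn. The other 8 lists did not without 1 or more sudachitin libraries, such as the unfolded protein response (0.14) without sudachitin ZT6 replicate 2 and lipid droplet genes (0.5) without sudachitin ZT18 replicate 1. The gene count was 15 without either control ZT6 library, 177 and 185 without control ZT18 replicate 1 or 2, 2 and 1 without sudachitin ZT6 replicate 1 or 2, and 5 and 12 without sudachitin ZT18 replicate 1 or 2. With total counts in place of TMM 8 genes were higher and 11 lower.

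The control and sudachitin calls shared 9 genes that rose and 10 that fell, against 0.034 in each direction for independent lists. Both comparisons used the same spread of each gene, which favours the same genes in both, so 0.034 is a low reference. The shared genes included Cry1, Wee1, Tspan4, G0s2 and Nmrk1 among those that rose and Nr1d1, Nr1d2, Dbp and Agxt among those that fell. Over both treatments together, 534 genes passed between ZT18 and ZT6 in edgeR, 270 higher and 264 lower. Their median size of change was 0.65 on the log2 scale in control and 0.63 in sudachitin livers, and 46.8% changed more in sudachitin livers. Of the core clock genes 4 rose and 2 fell, among them Arntl by 0.54 (SE 0.12, edgeR adjusted p = 0.045) and Per2 by 1.65 (SE 0.27, edgeR adjusted p = 0.016); adjusted over the list alone 6 rose and 3 fell. Of clock output genes 8 rose and 2 fell, of heat shock and cold-inducible genes 4 rose and 1 fell, of fatty acid oxidation genes 4 rose, of glycolysis and glycogen genes 4 rose and of unfolded protein response genes 7 fell. Adjusted over the list alone, 11 clock output genes rose and 3 fell, 11 heat shock and cold-inducible genes rose and 1 fell, 7 fatty acid oxidation and 6 glycolysis and glycogen genes rose, and in the unfolded protein response 12 fell and 1 rose. With camera 9 lists ranked higher and 3 lower at ZT18, with an adjusted p of 0.56 to 0.84 with an estimated correlation. With each library left out in turn, 6 of these 12 passed every time: clock output, fatty acid and triglyceride synthesis, lipid droplet and uptake, glycolysis and glycogen, the unfolded protein response, and heat shock and cold-inducible genes. Without control ZT18 replicate 1, oxidative phosphorylation (0.13) and fatty acid oxidation (0.32) did not. Over all 14506 genes the time effects of the 2 treatment groups correlated with r = 0.41 (Spearman 0.40), across genes. This r was 0.1 without control ZT18 replicate 2, 0.21 without sudachitin ZT18 replicate 1 and 0.27 without sudachitin ZT6 replicate 1. The count of 534 was 173 and 200 without control ZT6 replicate 1 or 2, 1048 and 259 without control ZT18 replicate 1 or 2, 164 and 212 without sudachitin ZT6 replicate 1 or 2, and 193 without sudachitin ZT18 replicate 1. On log2(FPKM + 0.1), limma called 141 genes higher and 267 lower.

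**Figure D2:**
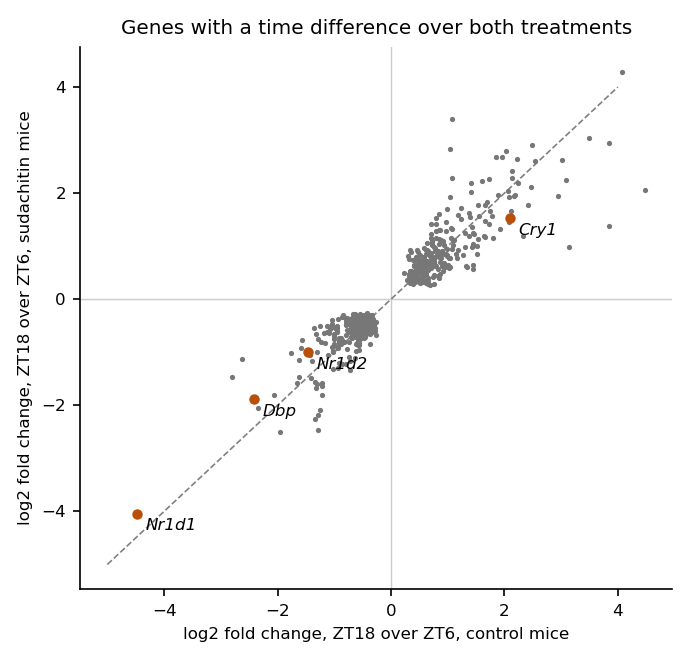
Log2 fold change from ZT6 to ZT18 in control livers (horizontal) and in sudachitin livers (vertical) for the 534 genes that passed over both treatments, with 4 clock genes named and the dashed line marking equal change. The genes were chosen by the effect averaged over both treatments, which favours changes of the same sign, and 46.8% of them changed more in sudachitin livers.

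At ZT6, sudachitin livers had higher mean levels of acute-phase transcripts, which liver makes in inflammation, although no gene passed over all genes in edgeR. Saa1, serum amyloid A1, was at 599 and 306 CPM in the 2 sudachitin livers and at 21.9 and 18.3 CPM in the 2 control livers, with a log2 difference of 4.49 (SE 0.84, edgeR adjusted p = 0.86). Saa2 differed by 5.08 (SE 0.92, adjusted p = 0.86) and Orm2, an orosomucoid, by 3.29 (SE 0.59, adjusted p = 0.86). Saa1 and Saa2, and Orm1 and Orm2, are near-identical copies whose reads the counting could split, so the value of each is uncertain. Of the 20 acute-phase genes none passed over all genes, and adjusted over the list alone 5 rose and 15 did not pass. Of 17 interferon response genes, all 17 were above 0, with Irf7 at 0.66 (SE 0.15, adjusted p = 1.0), and 1 rose when adjusted over the list alone. Of 17 macrophage and Kupffer cell markers 15 were above 0, with a median of 0.58, and none passed with either adjustment. Examples were Marco at 1.43 (SE 0.52, adjusted p = 1.0) and Clec4f at 0.58 (SE 0.23, adjusted p = 1.0). All 29 fatty acid oxidation genes were below 0 with a median of -0.13, and 23 of 24 cholesterol synthesis genes were below 0 with a median of -0.25; none of them passed with either adjustment.

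The count at ZT6 was 0 genes in edgeR, with 308 at an unadjusted p under 0.05, where 725 would pass by chance. A number under the chance one, here and in later comparisons, does not show that there was no effect, since genes are not independent. The spread was shared with control ZT18, where the chi-square per degree of freedom was 58.8, against 17.5 in control ZT6 and 19.9 in sudachitin ZT6. In the ZT6 groups alone edgeR called 10 genes, and with all 8 libraries DESeq2 called 9. The 9 were Saa1 (DESeq2 adjusted p = 0.005), Saa2 (0.0019), Orm1 (0.005), Orm2 (0.028), Apol9a (0.00041), Lars2 (4.6e-08), Gm42418 (5.5e-14), AY036118 (5.5e-14) and CT010467.1 (0.028). With camera, acute phase (adjusted p = 2.1e-08), interferon response (5.7e-07), macrophage markers (1.1e-06) and cell cycle (0.023) ranked higher. Fatty acid oxidation (0.0025), unfolded protein response (0.0025), cholesterol synthesis (0.011), fatty acid and triglyceride synthesis (0.011) and fibrosis and stellate cell genes (0.011) ranked lower. With an estimated correlation the adjusted p was 0.86 for each. Acute phase and interferon response passed with each library left out in turn, and the other 7 did not. Macrophage markers were at 0.23 without sudachitin ZT6 replicate 2, the unfolded protein response at 0.74 without control ZT6 replicate 2, fatty acid and triglyceride synthesis at 0.91 without control ZT6 replicate 1, and fatty acid oxidation at 0.31 without sudachitin ZT6 replicate 1. The edgeR count was 3, namely Orm2, AY036118 and Gm42418, without either control ZT18 library, which the comparison does not use except for the shared spread. The core clock list did not rank apart from other genes (camera adjusted p = 0.48). Camera looks for a shift in a common direction, while core clock genes moved in both directions between times, so this cannot exclude a clock change. Of the 15 core clock members, 13 differed by less than 0.5 on the log2 scale, and the smallest edgeR p adjusted over the list alone was 0.29.

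**Figure D3:**
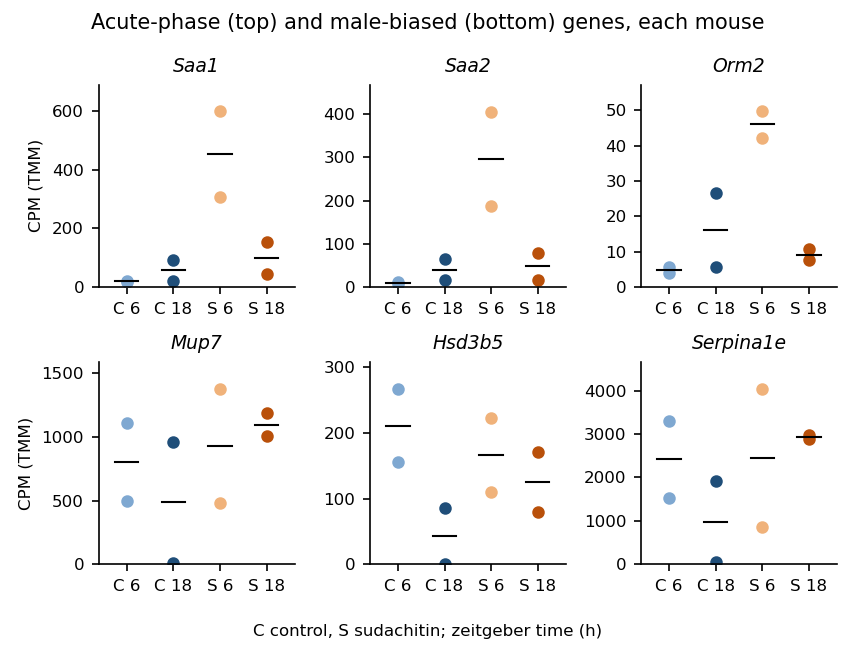
Expression in CPM (TMM-scaled, linear axis from 0) of the acute-phase genes Saa1, Saa2 and Orm2 (top) and the male-biased genes Mup7, Hsd3b5 and Serpina1e (bottom) in each mouse, for control (C) and sudachitin (S) livers at ZT6 and ZT18. Each point is 1 mouse and each bar the mean of 2 mice; Saa1 was at 599 and 306 CPM in the sudachitin ZT6 livers, and Mup7 at 14.3 CPM in control ZT18 replicate 1 against 485 to 1380 CPM in the other 7 livers.

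At ZT18, 2 genes passed in edgeR, and both lie in the ribosomal DNA unit on chromosome 17. Gm42418 rose by 1.87 (SE 0.17, edgeR adjusted p = 0.017) and AY036118 by 1.88 (SE 0.17, adjusted p = 0.017). Of 22 genes of the unfolded protein response 16 were above 0 with a median of 0.37, none passed over all genes and 1 rose when adjusted over the list alone; Xbp1 was at 0.61 (SE 0.13, adjusted p = 0.51) and Chac1 at 2.09 (SE 0.58, adjusted p = 0.69). Of 22 genes of fatty acid and triglyceride synthesis 19 were below 0 with a median of -0.37 and none passed with either adjustment, with Gpam, the first enzyme of glycerolipid synthesis, at -0.83 (SE 0.22, adjusted p = 0.65) and Fasn, fatty acid synthase, at -1.17 (SE 0.44, adjusted p = 0.72). All 16 fibrosis and stellate cell genes were below 0, with Col1a1 at -1.23 (SE 0.41, adjusted p = 0.71), and none passed with either adjustment. Of 15 core clock genes 13 differed by less than 0.5, none passed, and Npas2, a partner of BMAL1, was at -2.15 (SE 0.54, adjusted p = 0.59), with 0.054 when adjusted over the list alone. Its control value rests on 2 unlike libraries, 5.19 CPM in control ZT18 replicate 1 and 2.11 CPM in replicate 2. Without replicate 1 the difference was -1.34 (adjusted p = 1.0), and without replicate 2 it was -2.64 and passed (adjusted p = 0.038).

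At ZT18 the DESeq2 count was 49 and 945 genes had an unadjusted p under 0.05 in edgeR, where 725 would by chance. Among the 49 were the list members Gpam (log2 change -0.83, DESeq2 adjusted p = 0.036), Srebf1 (-1.03, 0.036), Chac1 (2.11, 0.036) and Angptl4 (1.03, 0.022), none of which edgeR called. With camera, male-biased genes (adjusted p = 2.7e-06) and the unfolded protein response (0.00042) ranked higher in sudachitin livers. Fibrosis and stellate cells (0.00013), cell cycle (0.00013), fatty acid and triglyceride synthesis (0.00032), xenobiotic phase 2 and NRF2 targets (0.00032), oxidative phosphorylation (0.0031), lipid droplet and uptake (0.0038) and female-biased genes (0.0051) ranked lower. With an estimated correlation the adjusted p was 0.75 for each. Of the 6 female-biased genes 4 fell when adjusted over the list alone. The control group at this time holds the library with low male-biased genes: Serpina1e was at 52.4 CPM in it and at 864 to 4030 CPM in the other 7 libraries, Hsd3b5 at 0.837 against 79.2 to 266, and the female-biased Cyp2b9 at 309 against 0.352 to 26.5. Serpina1e, Mup7 and Cyp2b9 belong to families of close copies, which makes their counts uncertain. Without that library, control ZT18 replicate 1, the unfolded protein response (adjusted p = 4e-06), fatty acid and triglyceride synthesis (0.00015) and fibrosis genes (0.0024) passed, and the other 6 lists did not, at 0.4 to 0.76; 2 genes passed. Without control ZT18 replicate 2, which leaves that library as the control, the unfolded protein response (0.3) and fatty acid and triglyceride synthesis (0.092) did not pass, so that fibrosis genes alone of the 9 lists passed with each library left out in turn. In that setting 194 genes passed, 90 higher and 104 lower, and the count was 0 without either control ZT6 or either sudachitin ZT18 library.

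Averaged over both times, 3 genes passed in edgeR, all higher in sudachitin livers, and 2 of them lie in the ribosomal DNA unit. Gm42418 rose by 1.67 (SE 0.13, edgeR adjusted p = 0.0022), from 2280 ± 215 CPM in control to 7280 ± 1110 CPM in sudachitin livers (mean ± SD, n = 4 mice each), and AY036118 by 1.67 (SE 0.13, adjusted p = 0.0022). Gm42418 was singled out after its values were seen, since the rule for named genes leaves out predicted symbols. Gm42418 lies at 39846958 to 39848788 on chromosome 17, GRCm38, in the ribosomal RNA repeat, and AY036118 at 39847113 to 39848035 on the opposite strand within it, so that the 2 cannot be counted apart without strand. Gm26917, beside them at 39843013 to 39846341, did not separate the groups, with 29.8 to 70.5 CPM in control and 42.7 to 92.3 CPM in sudachitin livers and a log2 ratio of 0.6 (SE 0.39, exact two-sided permutation p = 0.17). Lars2, mitochondrial leucyl-tRNA synthetase, at 123366927 to 123462664 on chromosome 9, rose by 1.33 (SE 0.12, adjusted p = 0.0068), from 325 ± 55.8 to 818 ± 129 CPM. Gm42418 held 0.23% of counts in control and 0.73% in sudachitin livers, and its 4 control values, 2040 to 2520 CPM, lay below its 4 sudachitin values, 5810 to 8410 CPM. DESeq2 called 15 genes, and 640 had an unadjusted p under 0.05 in edgeR, where 725 would by chance. The edgeR count was 6 without sudachitin ZT18 replicate 2.

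**Figure D4:**
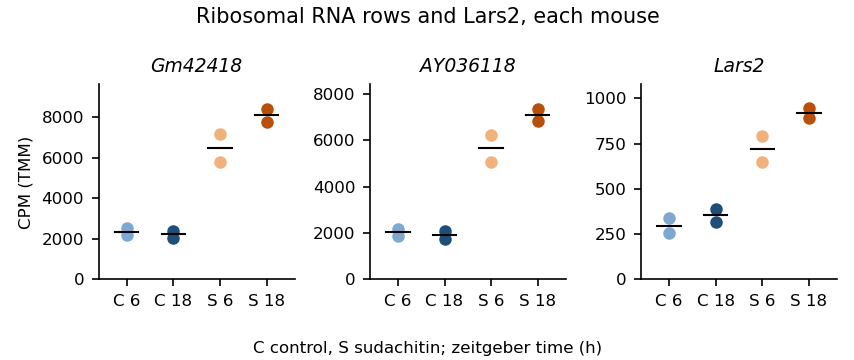
Expression in CPM (TMM-scaled, linear axis from 0) of Gm42418, AY036118 and Lars2 in each mouse, for control (C) and sudachitin (S) livers at ZT6 and ZT18; each point is 1 mouse and each bar the mean of 2 mice. The 4 control livers sat between 2040 and 2520 CPM for Gm42418 and the 4 sudachitin livers between 5810 and 8410 CPM.

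Gene lists were also compared over both times. With camera, fibrosis and stellate cells (adjusted p = 5.2e-06, median -0.44), fatty acid and triglyceride synthesis (1.1e-05, median -0.35), lipid droplet and uptake (0.00049), fatty acid oxidation (0.00076), glycolysis and glycogen (0.012), female-biased genes (0.02), sinusoidal endothelial markers (0.035), adipocyte markers (0.037) and cholesterol synthesis (0.04) ranked lower in sudachitin livers. Acute phase (1.2e-05, median 0.25), macrophage markers (0.0013), interferon response (0.0019) and male-biased genes (0.014) ranked higher. With an estimated correlation none passed, with an adjusted p of 0.44 to 0.82. No member of these 13 lists passed over all genes in edgeR. DESeq2 called Gpam, of fatty acid and triglyceride synthesis, at -0.67 (DESeq2 adjusted p = 0.024) and Socs3, of acute phase, at 1.02 (0.016). In edgeR adjusted over the list alone, 2 acute-phase and 1 interferon gene rose and 1 gene of fatty acid and triglyceride synthesis fell. Without control ZT18 replicate 1, 6 of the 13 passed: acute phase (2.5e-11), macrophage markers (2e-10), interferon response (1e-09), fatty acid and triglyceride synthesis (1.1e-05), fibrosis (2e-05) and glycolysis (0.015). The male-biased list, at 0.56 without that library, then ranked lower. With each library left out in turn, fatty acid and triglyceride synthesis, acute phase and fibrosis genes passed every time. Macrophage markers were at 0.52 and glycolysis at 0.072 without sudachitin ZT6 replicate 2, and interferon response was at 0.11 without control ZT18 replicate 2.

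The interaction asks whether the change from ZT6 to ZT18 differed between treatments. The unfolded protein response ranked higher in it, with 18 of its 22 members above 0 and a median difference of 0.54 (camera adjusted p = 4.9e-06, and adjusted p = 0.92 with an estimated correlation). Its change from day to night was thus less negative in sudachitin than in control livers. Without control ZT18 replicate 1 this list had an adjusted p of 2.4e-08, and the other 7 lists that passed for the interaction did not; it passed with each library left out in turn. Xbp1 differed by 0.95 (SE 0.18, edgeR adjusted p = 0.88), Hspa5, the chaperone BiP, by 0.86 (SE 0.29, adjusted p = 1.0) and Calr by 0.58 (SE 0.20, adjusted p = 1.0); none of the 22 passed over all genes, and 1 rose when adjusted over the list alone. Of the 15 core clock genes none passed: Npas2 differed by -2.69 (SE 0.74, adjusted p = 1.0), Per1 by 1.07 (SE 0.30, adjusted p = 1.0), Cry1 by -0.58 (SE 0.20, adjusted p = 1.0) and Nr1d2 by 0.46 (SE 0.18, adjusted p = 1.0). These 4 had an unadjusted p under 0.05, and the smallest p adjusted over the list alone was 0.0504. For Npas2 the difference was -1.89 without control ZT18 replicate 1 and -2.03 without sudachitin ZT6 replicate 2. In edgeR 0 genes passed the interaction, 548 had an unadjusted p under 0.05, where 725 would by chance, and DESeq2 called 14, among them Xbp1 (DESeq2 adjusted p = 0.045), Angptl4 (0.042) and Mcm10 (0.0045). The edgeR count was 13 without control ZT18 replicate 2, 9 higher and 4 lower. Across genes, the sudachitin effects at ZT6 and ZT18 correlated with r = 0.01 (Spearman 0.01), and with -0.07 to 0.06 when each library was left out in turn. The median size of the effect was 0.12 at ZT6 and 0.17 at ZT18, below the median SE of 0.21. An r near 0 therefore cannot tell effects that differ between times from noise.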

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

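Among the tests reported in this part, the one for a female animal was chosen before the values it measures were seen, while those for another time of day, for another treatment, for fewer hepatocytes, for growth hormone signalling, for macrophages and for a shared event were chosen after.

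In 8 gene lists the effect of sudachitin differed between ZT18 and ZT6, by camera on the interaction with the preset correlation, and none of the 8 passed with an estimated correlation (adjusted p = 0.92 for each). The effect was higher at ZT18 for male-biased genes (adjusted p = 1.6e-06, 18 of 18 members above 0, median log2 difference 1.17) and for the unfolded protein response (adjusted p = 4.9e-06, 18 of 22 above 0, median 0.54). Lower at ZT18 were cell cycle (adjusted p = 5.1e-06, 16 of 18 below 0), xenobiotic phase 2 and NRF2 targets (0.00016, 20 of 22 below 0), interferon response (0.0022, 15 of 17 below 0), macrophage and Kupffer cell markers (0.005, 15 of 17 below 0), oxidative phosphorylation (0.005, 38 of 42 below 0) and acute phase (0.021, 14 of 20 below 0). Without control ZT18 replicate 1 the unfolded protein response passed at 2.4e-08, and the others had an adjusted p of 0.059 for cell cycle and male-biased genes, 0.17 for phase 2 and NRF2 targets, 0.35 for oxidative phosphorylation and 0.59 for interferon response, macrophage markers and acute phase. Macrophage markers also failed without sudachitin ZT6 replicate 2 or sudachitin ZT18 replicate 2. Oxidative phosphorylation also failed without control ZT6 replicate 1 or sudachitin ZT18 replicate 2. Acute phase also failed without control ZT6 replicate 2, sudachitin ZT6 replicate 2 or sudachitin ZT18 replicate 2. For the unfolded protein response the library means of the log2 deviation from the average were 0.19 and 0.55 in control ZT6, -0.31 and -0.58 in control ZT18, 0.10 and 0.16 in sudachitin ZT6 and -0.05 and -0.06 in sudachitin ZT18 livers.

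Control ZT18 replicate 1 had low male-biased and high female-biased transcripts, with Slco1a1 at 26.7 CPM against 325 to 492 CPM in the other 7 libraries. A female animal under this label is argued against by the summed Y-linked transcripts Ddx3y, Eif2s3y, Kdm5d and Uty, at 0.948 times the median of the others, and a ZT6 mouse by Nr1d1 at 0.957 times the other ZT18 control. Fewer hepatocytes are argued against by 7 abundant hepatocyte transcripts, whose median log2 difference from the other ZT18 control was -0.03, while male-biased genes stood at -1.98. More of some other cells in this sample was not excluded: as mean log2 deviations from the average, with the other ZT18 control in brackets, adipocyte markers were at 1.16 (-0.05), erythroid and blood markers at 0.66 (-0.28), macrophage markers at 0.45 (-0.31), fibrosis and stellate cell genes at 0.45 (0.2), cholangiocyte markers at 0.06 (0.38) and lymphocyte markers at -0.37 (0.27). A sudachitin mouse under this label stays open: in edgeR fitted without this library, 3 genes passed between treatments over both times, and they were Gm42418, AY036118 and Lars2. This library lay below all 4 sudachitin libraries in each, with Gm42418 at 2384 CPM against 5806 to 8407, AY036118 at 2102 against 5083 to 7372 and Lars2 at 387.8 against 650 to 943.5. These values argue against such a mouse only if the transcripts follow the treatment and not the library preparation, which was not settled. Lower growth hormone signalling in this animal stays open as a hypothesis, because Igf1, Igfals, Socs2 and Cish had a median log2 difference of -0.79 from the other 7 libraries and of 0 from the other ZT18 control. Sudachitin ZT6 replicate 2 leaned the same way, with a mean log2 deviation of -0.57 for male-biased genes (-2.43 in control ZT18 replicate 1, -0.05 to 0.91 in the other 6 libraries) and of 0.42 for female-biased genes (2.88, and -1.44 to 0.13 in the other 6). Selenbp2 was at 15 CPM in it and at 14.6 CPM in control ZT18 replicate 1, and Cyp4a12a at 36.9 and 112 CPM. With so few mice, a property of the animal cannot be set apart from one of its handling. The treatment tests of the male-biased and female-biased lists, given above, do not separate them either.

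Acute-phase transcripts were high in both sudachitin ZT6 livers. Saa1 was at 153 and 42.5 CPM in the sudachitin ZT18 livers and at 93.5 and 18.9 CPM in the control ZT18 livers. The higher control was replicate 1, the library that stood apart, so a mouse labelled control also had raised acute-phase transcripts. Its Lcn2 was at 29 CPM, against 37.3 and 27.9 in sudachitin ZT6 livers and 4.78 in the other ZT18 control. Its Orm2 (26.7 CPM) and Saa2 (63.6 CPM) lay above that control (5.76 and 16.6) but below both sudachitin ZT6 livers. More macrophages in the sudachitin ZT6 samples stay open: their 17 markers had a median log2 difference of 0.58 with a median absolute deviation of 0.27. Saa1, Saa2, Orm2 and Lcn2 differed by at least 2.99. More macrophages alone, by as much as the markers rose, would fall short of the changes of these 4 genes. The test's stricter bound, chosen after the values were seen, was not met. This test replaced one on Saa3, which stood at 1.17 to 5.3 CPM and was too low to decide. A shared event, such as a cage or handling group, cannot be told apart from the treatment, since the title codes of the ZT6 sudachitin mice begin in only 1 way. An effect of sudachitin that differs by time of day is the biological explanation the design gives. It stays a hypothesis because the acute-phase list of the interaction was lost with an estimated correlation. That list was also lost without control ZT18 replicate 1, control ZT6 replicate 2, sudachitin ZT6 replicate 2 or sudachitin ZT18 replicate 2.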

How the results depend on the processing

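Of the alternatives, the one without Gm42418, AY036118, CT010467.1 and Lars2 was chosen after the data were seen. Counts within 1.5 times of the reported ones are not repeated, and the cause was not tested for any count below unless its construction shows it. DESeq2 gave 9 genes for treatment at ZT6, 49 for treatment at ZT18, 262 for time in control, 274 for time in sudachitin livers, 14 for the interaction, 15 for treatment and 942 for time over both levels. Without a filter on low counts edgeR gave 67, 488, 881, 861, 259, 309 and 1629 in the same order. With only the groups compared, which leaves 4 libraries, it gave 10 at ZT6, 0 at ZT18, 4 for time in control and 53 for time in sudachitin livers. Against a fold of 1.2 it gave 37 for time in control, 16 for time in sudachitin livers and 138 for time over both treatments. On log2(FPKM + 0.1), and on log2(FPKM + 1), limma gave 0 at ZT18 and 41 for time in control; with every gene above 0 it gave 2 at ZT6, 18 at ZT18, 15 for time in control, 1 for treatment over both times and 141 for time over both treatments. Without Gm42418, AY036118, CT010467.1 and Lars2 it was 0 at ZT18 and 0 for treatment over both times, since those genes were left out. With the replicate number as a block the count was 1 at ZT6, 0 at ZT18 and 43 for time in control. Same-numbered mice deviated from their group means with r of -0.2 to 0.28 across genes, the highest between control ZT18 and sudachitin ZT18. With 2 mice per group this cannot exclude that same-numbered mice shared a batch or handling. The block kept every list call but 1 of 13 for treatment over both times. Leaving out 1 library in turn gave 0 to 3 genes at ZT6, 0 to 194 at ZT18, 5 to 323 for time in control, 1 to 185 for time in sudachitin livers, 0 to 13 for the interaction, 2 to 6 for treatment and 164 to 1048 for time over both levels. The correlation of treatment effects between times ranged from -0.07 to 0.06 and that of time effects between treatments from 0.1 to 0.48. Of 49 calls of named genes, 49 were kept by DESeq2, 48 with median-of-ratios factors, 41 with total counts, 49 without a filter on low counts, 44 with the filter of 5 CPM, 20 with only the groups compared, 30 with the block, 28 against a fold of 1.2, 28 on log2(FPKM + 0.1), 27 on log2(FPKM + 1), 15 on log2(FPKM + 0.1) with every gene above 0 and 14 to 48 without 1 library. Without Gm42418, AY036118, CT010467.1 and Lars2, 48 of 48 were kept. No call reversed; of 12785 comparisons of named genes past the threshold in neither fit, 163 had another sign. No list call of any comparison was kept with an estimated correlation; fry kept 3 of the 12 for time over both treatments and none elsewhere. With 13914116 to 17759630.5 counts per library and 2 mice per group, changes of a fold of 2 were found in 12% of simulated cases for the interaction.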

Other observations

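Among the tests reported in this part, those on small nuclear, 7SK and mitochondrial ribosomal RNA and on overlapping transcripts were chosen after the values were seen, and those on histone genes and on other splits before, while the limit to balanced splits was set after.

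In control livers several other genes differed between night and day. Fmo2, a flavin-containing monooxygenase, rose by 2.32 on the log2 scale from ZT6 to ZT18 (SE 0.31, edgeR adjusted p = 0.022). Ces1d, a carboxylesterase with close copies, rose by 1.66 (SE 0.20, adjusted p = 0.015), and Clec2h fell by 3.87 (SE 0.63, adjusted p = 0.045). The control ZT18 mean behind these values includes the library that stood apart. None of these genes passed in sudachitin livers, where Fmo2 rose by 1.2 and Ces1d by 1.17. In sudachitin livers Jade1 fell by 1.11 (SE 0.12, adjusted p = 0.011) and Mrnip by 1.58 (SE 0.19, adjusted p = 0.023), and Lonrf1 rose by 1.22 (SE 0.17, adjusted p = 0.042). Mrnip also passed in control livers, with a fall of 1.21 (SE 0.18, adjusted p = 0.036). Of 18 bile acid genes, 2 fell and 16 did not pass in control livers, and 18 did not pass in sudachitin livers; adjusted over the list alone, 1 rose and 4 fell in control and 2 rose and 5 fell in sudachitin livers. The list did not rank apart from other genes (camera adjusted p = 0.072 in control and 0.33 in sudachitin livers).

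Several lists of other cell types and of liver zones did not rank apart between treatments. For lymphocytes the camera adjusted p was 0.66 at ZT6 and 0.15 at ZT18, for cholangiocytes 0.8 and 0.81, for erythroid and blood genes 0.25 and 0.14, for periportal hepatocytes 0.41 and 0.73 and for pericentral hepatocytes 0.71 and 0.26, and no member of these lists passed over all genes or adjusted over the list alone. Clock output genes (camera adjusted p = 0.74 and 0.14) likewise did not rank apart between treatments. Their list holds genes that rose and genes that fell between times, and camera can miss changes in opposite directions.

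Gm42418, AY036118, CT010467.1 and Lars2 were higher in sudachitin livers at both times. Gm42418 and AY036118 may be counts of the same reads, since the log2 ratio between them varied over the 8 libraries by an SD of 0.0086, while log2 Gm42418 varied by 0.91. More RNA without a poly(A) tail in the sudachitin libraries stays open: summed small nuclear, small Cajal body and 7SK RNA had a log2 ratio of 0.75 (SE 0.35, exact two-sided permutation p = 0.11). Within it the 7SK transcript Rn7sk had one of 1.58 (SE 0.34, exact two-sided permutation p = 0.029), at 0.654 to 1.12 CPM in control and 1.98 to 4.82 CPM in sudachitin livers; over both times DESeq2 called it (adjusted p = 0.012) and edgeR did not (0.58). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 had log2 ratios of 0.25 (SE 0.26, exact two-sided permutation p = 0.43) and 0.27 (SE 0.23, p = 0.31). Histone genes had one of 0.17 (SE 0.11, exact two-sided permutation p = 0.17), where 0.029 is the smallest p that 4 against 4 can give. The histone sum was not limited to genes without a poly(A) tail, since it held H1f0, so it cannot settle this. Lars2 rose together with Gm42418 and AY036118, and whether its counts include reads of ribosomal RNA was not tested. An effect of sudachitin on ribosomal RNA is the biological explanation the design gives, and it cannot be told apart from a difference in poly(A) selection, since the labels give no library batch.

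Other splits of the 8 libraries into 4 and 4 were tested in the additive model, with 2 libraries of each level of the other factor on each side. There are 18 such splits, which are too few for a share under 0.05. For treatment the real split gave 3 genes, 2 of which may be the same reads, and the others at most 1. For time it gave 534 genes and the others at most 1.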
